A study of Homo sapiens with 24 samples.

How the data were processed

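Gene expression was measured on Affymetrix arrays in 24 RNA samples from 2 B-lymphoblastoid cell lines, GM10855 and GM10861. They are HapMap project lines of B cells transformed with Epstein-Barr virus. Each line was sampled untreated at 0 h or after 36 h with calcitriol (the hormonal form of vitamin D), with estrogen, or with both, giving 8 groups of 3 arrays. Per the labels' protocols, RNA was extracted with an Exiqon kit, and biotinylated cDNA was prepared from total RNA by the whole-transcript protocol of the array maker. The doses, the estrogen compound, the vehicle and the culture conditions are not given in the sources used here. The series text also mentions ENCODE cell lines, which were not analysed here.

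The deposited values are log2 signals per probe set, made by the authors with RMA in Affymetrix Expression Console 1.0.1, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays equal and summarises the probes of a probe set, so a change shared by most genes is removed and fold changes of dim probe sets are compressed. Which arrays were normalised together, the genome build and the annotation are not given in the sources used here. The table held 33297 probe sets on every array. No detection p-values came with it, so no background limit was applied and low signals were kept. The number of arrays limits the precision.

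Gene names came from a probe table, which gave 19460 probe sets 1 symbol, 1754 several symbols and 12083 none; those 12083 are unnamed here. Of the single-symbol probe sets, 19429 matched a gene of the GRCh38.p14 gene table by Entrez ID, which was used for names and for which genes neighbour each other. Because the build behind the probe sets is not given, no coordinates are printed. The tests covered the 21214 probe sets with at least 1 symbol. For gene lists, 1 probe set per gene was kept, that with the highest mean over all arrays, leaving 18417 genes.

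Differential expression was tested in R 4.3.3 with limma 3.58.1 on the deposited log2 values without further normalisation. The model had 1 mean per group over all 24 arrays, which leaves 16 residual degrees of freedom, and eBayes added 6.73 prior degrees of freedom. Contrasts were averaged over both lines, each line being compared with itself. Those contrasts were calcitriol against untreated, estrogen against untreated, calcitriol and estrogen against untreated, calcitriol added to estrogen (both agents against estrogen alone), estrogen added to calcitriol (both agents against calcitriol alone) and the interaction of the agents. Further contrasts took each line by itself and the difference in response between lines, coded as GM10861 minus GM10855. P-values were two-sided and adjusted by the Benjamini-Hochberg method within a contrast, and a probe set was called at an adjusted p under 0.05. Every p-value measures the spread between these arrays, which may be technical replicates, since the sources used here do not say whether the 3 arrays of a group came from separate cultures. Arrays of a group are numbered in the order of the sample list, and the numbers pair no arrays. Errors of log2 changes are standard errors from limma, and errors of group means are standard deviations.

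A total of 31 gene lists with 799 entries, of which 718 were measured, were tested with camera, a competitive test in limma that compares a list with all other genes, at a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment ran over the lists of a comparison. For each list, the members past the threshold were counted over all probe sets and again adjusted over the list alone. The list test with an estimated correlation, and fry, which asks whether the members move on balance one way without comparing them with other genes, served as alternatives.

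The samples in each group, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the 10 largest rises and 10 largest falls were named among probe sets with 1 symbol, past the threshold and changed the same way in both lines. Where none passed, the 3 with the smallest p in each direction were named. Added to these were up to 5 line differences in each direction past the threshold, up to 4 members with the smallest p in each list described, and always VDR, RXRA, CYP24A1, CYP27B1, CAMP, ESR1 and ESR2. Y-linked genes, immunoglobulin and T cell receptor segments, HLA-DRB genes, genes with common whole-gene deletions, predicted loci, small RNAs and pseudogenes were not named.

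The alternatives were a filter that kept the 14526 probe sets with a mean log2 signal of at least 5, all probe sets with or without a symbol, centring each array on its median, cyclic loess between arrays, eBayes with trend and robust estimation, array weights, a fit of only the arrays compared, a minimum absolute log2 change of 0.5, and leaving out each array in turn. Gene lists were also tested with the mean of all probe sets of a gene. Chosen after seeing the data were fits without the 3 arrays farthest from their group means (which leaves 1 untreated array of GM10855), the estrogen arrays in place of the untreated arrays, the response to both agents in each line by itself, and the line differences with both agents against untreated and in calcitriol added to estrogen.

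The procedure was tested on simulated data of the 21214 probe sets, with 200 probe sets changed in each of 5 runs. They were made from the mean of each cell line over all its arrays. The spread within groups of each probe set was pooled, so both lines had the same simulated spread. For calcitriol against untreated it recovered 31.9%, 91.0% and 100.0% of the changes of log2 0.25, 0.5 and 1, and 4.87% of the calls were false. For calcitriol added to estrogen the shares were 30.7%, 89.9% and 99.7%, with 4.56% false calls. Within GM10855 alone they were 5.07%, 61.2% and 98.2%, with 5.54% false calls. In other contrasts the simulated changes did not enter or cancelled, so every call was false. The same 5 runs gave 0 such calls for estrogen against untreated, 1 for the interaction and 0 for the line difference in the calcitriol response. A list raised by log2 0.2 was called in 5 of 5 runs, and 0 other lists were called. The simulated noise was independent between probe sets, so these runs cannot show how often lists with correlated members are called falsely.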

Results

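The data were expression profiles of 2 human B-lymphoblastoid lines, GM10855 and GM10861, exposed to calcitriol, to estrogen or to both for 36 h and compared with untreated cells at 0 h. Calcitriol is the ligand of the vitamin D receptor VDR, and estrogen acts through the receptors ESR1 and ESR2. The 24 arrays formed 8 groups of 3. Array medians lay between 5.38 and 5.50 on the log2 scale, and arrays of the same group correlated at 0.985 to 0.993 across probe sets, against 0.978 to 0.984 between the lines. No pair of arrays was identical (0 pairs). The median standard deviation between the 3 arrays of a group was 0.137 in GM10855 and 0.115 in GM10861. A change averaged over both lines had a median standard error of 0.0742 and a median 95% interval of 0.154 on either side. Untreated cells were sampled at 0 h alone, so a change against them holds the agent and 36 h of culture together, whereas comparisons among treated groups were matched for time. VDR itself gave a low signal in untreated cells, 4.98 ± 0.145 in GM10855 and 4.92 ± 0.0612 in GM10861 (SD, n = 3), near percentile 35.2 of probe sets. ESR1 lay near percentile 21.3 and ESR2 near percentile 30.0, and no background limit was at hand to say whether such signals exceed noise.

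The first comparison asked which genes changed with calcitriol on average over both lines, and a call did not require a response in each line. CAMP, which encodes the antimicrobial peptide cathelicidin, had the largest measured rise in calcitriol against untreated, 5.50-fold (log2 change 2.46 ± 0.102, SE, adjusted p = 1.21e-13, Entrez 820). Its mean went from 5.98 ± 0.290 to 8.61 ± 0.127 in GM10855 and from 5.74 to 8.04 in GM10861 (SD, n = 3). CYP24A1, the 24-hydroxylase that inactivates calcitriol, rose 4.16-fold (2.06 ± 0.115, adjusted p = 3.89e-11, Entrez 1591). Its untreated means of 3.30 in GM10855 and 3.69 in GM10861 lay below the lower quartile of every array (3.97 at the lowest), where RMA compresses folds, so its rank below CAMP is not settled. STS, the steroid sulfatase that frees steroids from their sulfate esters, rose 3.70-fold (1.89 ± 0.0607, adjusted p = 8.18e-16, Entrez 412). CD38, a surface enzyme that hydrolyses NAD and marks plasma cells, rose from 8.42 ± 0.173 to 9.26 ± 0.0587 in GM10855 and from 7.34 ± 0.112 to 8.51 ± 0.0305 in GM10861 (SD, n = 3; adjusted p = 2.58e-10 in limma). CD79A, a signalling chain of the B cell receptor, rose by a log2 change of 0.85, and SLC25A20, the mitochondrial carnitine-acylcarnitine carrier, by 0.90. The other genes among the 10 largest rises were DENND6B (1.05), the zinc finger gene ZNF589 (0.93), the lysosomal protease LGMN (0.83) and CLMN (0.80). VDR rose 1.36-fold (0.44 ± 0.0623, adjusted p = 2e-04). In all, limma called 144 of 21214 probe sets, 131 higher and 13 lower, covering 120 and 13 genes, and 31 of the calls reached an absolute log2 change of 0.5. Each of the 23 named rises was higher in 6 of 6 calcitriol arrays than the untreated mean of its line.

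**Figure D1:**
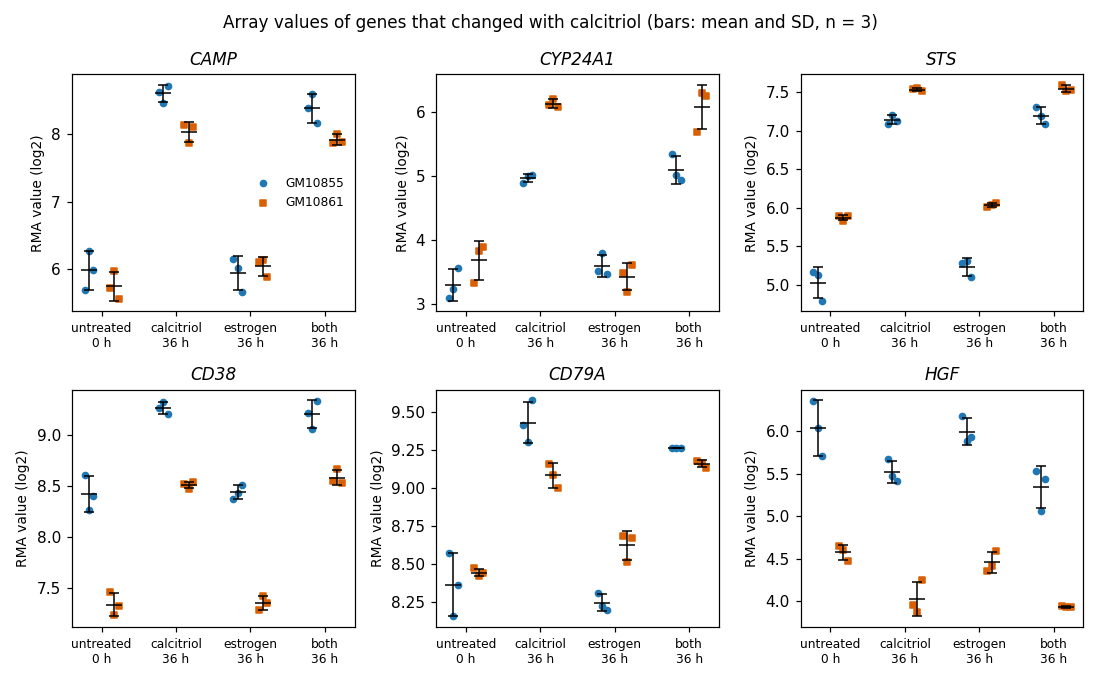
Log2 signal on each array for CAMP, CYP24A1, STS, CD38, CD79A and HGF in GM10855 and GM10861, by agent. Points are single arrays, and bars give the mean and SD of each group (n = 3); CAMP means were 5.98 untreated and 8.61 with calcitriol in GM10855, while HGF was lower with calcitriol in both lines.

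Genes that fell were fewer and changed less. HGF, which encodes hepatocyte growth factor, had the largest fall in calcitriol against untreated, a log2 change of -0.53 ± 0.0975 (adjusted p = 0.00483), followed by the chemokine receptor CCR2 at -0.44 (adjusted p = 0.0131) and TOX, a nuclear factor of lymphocyte development, at -0.39 (adjusted p = 0.0112). ANXA1, an anti-inflammatory annexin, fell by 0.38 on the log2 scale, the cytokine gene IL21 by 0.34, and IL10RA, which encodes the interleukin-10 receptor chain, by 0.32. FRMD6 changed by -0.34, the myosin gene MYO5C by -0.32, CCDC88A by -0.29 and DUS4L by -0.26. All 10 were lower in 6 of 6 calcitriol arrays, and none of the 10 kept its call in every alternative (0 kept). HGF, TOX and MYO5C kept theirs whichever single array was left out, but lost them without the 3 arrays farthest from their group means (adjusted p = 0.0811, 0.183 and up to 0.132), MYO5C also in a fit of only the arrays compared. CCR2 lost its call only without untreated array 3 of GM10855 (adjusted p = 0.0538), and DUS4L in 11 of 12 such fits (up to 0.169). The other 5, in order ANXA1, IL21, FRMD6, IL10RA and CCDC88A, lost theirs in 5, 10, 7, 9 and 8 of 12 fits. A second CCR2 probe set gave -0.45 without passing (adjusted p = 0.198). In calcitriol added to estrogen, at matched times, HGF, CCR2 and ANXA1 were called lower as well. The others were not called there: FRMD6 gave -0.30, IL10RA -0.26, TOX -0.23, CCDC88A -0.17, DUS4L -0.12, MYO5C -0.11 and IL21 -0.0096. The fall of IL21 was thus not seen at matched times.

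Among the 31 gene lists, 15 passed camera in calcitriol against untreated, 13 toward higher and 2 toward lower expression; 3 of them passed with an estimated correlation. Known targets of the vitamin D receptor formed the first of these. Of 36 measured, 6 rose (7 adjusted over the list alone), led by CAMP, CYP24A1 and G0S2, an inhibitor of the lipase ATGL (0.53, adjusted p = 8.57e-05), with a mean of 0.21 against a median of 0.04 (adjusted p = 7.71e-09; adjusted p = 0.00802 with an estimated correlation). GADD45A, a stress-induced gene also held in the list of p53 targets, rose by 0.32 (adjusted p = 0.0199) and lost its call in 5 of 12 fits without 1 array (up to 0.0766). Of 18 B cell markers 3 rose (5 adjusted over the list alone): CD79A, the complement receptor CR2 (0.41, adjusted p = 5.51e-04) and the B cell transcription factor PAX5 (0.26, adjusted p = 0.0199), the last lost in 8 of 12 fits without 1 array (up to 0.0816). That list had a mean of 0.13 (adjusted p = 2.8e-07; adjusted p = 0.0254 with an estimated correlation). Of 15 plasma cell markers 2 rose, CD38 and TNFRSF17, which encodes the survival receptor BCMA (0.67, adjusted p = 8.18e-09). Adjusted over the list alone, 6 plasma cell markers were higher and 1 was lower, and CD27 (0.28, adjusted p = 0.0727 over all probe sets) and SDC1 (0.19, adjusted p = 0.353) did not pass. The plasma cell list had a mean of 0.15 (adjusted p = 3.19e-06; adjusted p = 0.0495 with an estimated correlation).

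The remaining lists that passed moved by small amounts and did not pass with an estimated correlation. LGMN was the 1 of 17 MHC class II presentation genes that rose (3 adjusted over the list alone; list adjusted p = 3.19e-06; adjusted p = 0.0649 with an estimated correlation). Of 35 NF-kB targets and inflammatory cytokines, 2 rose (6 adjusted over the list alone), the cytokine LTA (0.40, adjusted p = 0.00348) and the chemokine CCL22 (0.44, adjusted p = 0.0239); the list had an adjusted p = 1.12e-05 (adjusted p = 0.194 with an estimated correlation). CCL22 lost its call in 7 of 12 fits without 1 array (up to 0.0994), and the other LTA probe sets, at 0.30 and 0.26, did not pass (adjusted p = 0.0805 and 0.126). DDIT4, an inhibitor of mTORC1 (0.63, adjusted p = 2.9e-05), and PHGDH, which starts serine synthesis (0.40, adjusted p = 1.78e-04), were the 2 of 31 ATF4 targets that rose (2 adjusted over the list alone; list adjusted p = 0.0144; adjusted p = 0.293 with an estimated correlation). DDIT4 was also the 1 of 33 hypoxia and glycolysis genes (1 adjusted over the list alone; list adjusted p = 1.12e-05; adjusted p = 0.206 with an estimated correlation). From 33 genes at autoimmune disease risk loci, 2 rose (3 adjusted over the list alone), the transcription factors IRF8 (0.29, adjusted p = 0.0143) and IKZF1 (0.30, adjusted p = 0.0423). This list had an adjusted p = 0.0321 (adjusted p = 0.293 with an estimated correlation). IRF8 lost its call without untreated array 3 or calcitriol array 1 of GM10855 (up to 0.0566), and IKZF1 in 10 of 12 fits without 1 array (up to 0.147).

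No member was called over all probe sets in the NRF2, TFEB, unfolded protein response, fatty acid synthesis and immediate early gene lists (0 in limma for each, 2, 2, 0, 0 and 0 adjusted over the list alone). These lists leaned toward higher expression in calcitriol against untreated, with adjusted p = 0.119, 0.139, 0.294, 0.383 and 0.385 with an estimated correlation. HMOX1, the heme oxygenase of the NRF2 list, had a change of 0.24 (adjusted p = 0.506), and CTSB, cathepsin B of the TFEB list, 0.24 (adjusted p = 0.0618). Leaning lower were 31 G2/M and mitosis genes (mean -0.0615, adjusted p = 7.96e-05; adjusted p = 0.294 with an estimated correlation) and 41 interferon-stimulated genes (mean -0.0383, adjusted p = 0.0357; adjusted p = 0.516 with an estimated correlation). Among them the mitotic kinase genes CDK1 and AURKA had changes of -0.14 and -0.14, and the ADP-ribosyltransferase gene PARP9 -0.26, none past the threshold (adjusted p = 0.725, 0.752 and 0.112). Adjusted over the list alone, 0 G2/M genes and 1 higher and 1 lower interferon-stimulated gene passed. The interferon-stimulated, unfolded protein response, ATF4, fatty acid, immediate early and autoimmune lists each lost their call without at least 1 array (in 5, 5, 2, 6, 4 and 6 of 12 fits).

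Markers of other cell types did not pass with calcitriol. T cell, NK cell, monocyte, erythroid and fibroblast lists had 0 called members in limma and adjusted p = 0.869, 0.138, 0.458, 0.869 and 0.869; the monocyte median was above 0 while its mean and test were below. The list of 27 estrogen response genes had an adjusted p = 0.0551 and 0 called members. Among 15 estrogen receptors and cofactors, CYP19A1, the aromatase that makes estrogens from androgens, was the 1 that rose (0.46 ± 0.0829, adjusted p = 0.00436; 1 adjusted over the list alone), a call lost without the 3 arrays farthest from their group means (adjusted p = 0.0721). The list itself did not pass (adjusted p = 0.531). Vitamin D metabolism and receptor cofactor genes, 15 in number, held 2 rises, CYP24A1 and VDR, with a median of -0.0031, a mean of 0.15 and an adjusted p = 0.110. CYP27B1, the enzyme that makes calcitriol, gave 0.06 in calcitriol against untreated (adjusted p = 0.986), and RXRA, the partner of VDR, -0.12 (adjusted p = 0.847). ESR1 and ESR2 gave -0.07 and 0.01 (adjusted p = 0.979 and 0.999). Other lists outside the threshold ran up to an adjusted p = 0.995.

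Calcitriol was next compared in the presence of estrogen, with both groups at 36 h. CAMP again had the largest measured rise in calcitriol added to estrogen, 4.48-fold (2.16 ± 0.102, adjusted p = 1.97e-12), with CYP24A1 at 2.08 ± 0.115, STS at 1.74 ± 0.0607 and CD38 at 0.99 ± 0.0621. DENND6B (0.92), ZNF589 (0.90), CD79A (0.78), CLMN (0.77), SLC25A20 (0.71) and SULF2, a sulfatase acting on heparan sulfate (0.70), completed the 10 largest rises, and VDR rose by 0.31 (adjusted p = 0.0134). The VDR call was lost without array 3 of GM10861 with both agents (adjusted p = 0.0540) and in a fit of only the arrays compared (adjusted p = 0.0591). HGF fell by 0.59 on the log2 scale (adjusted p = 0.00165), CCR2 by 0.55 and ANXA1 by 0.51, and HAPLN3, a matrix link protein gene, by 0.34; these 4 falls kept their calls in every setting that tested them, the minimum change of 0.5 aside, and the filter on dim probe sets left out HGF and CCR2. The mitotic phosphatase gene CDC25C at -0.29, CD109 at -0.29, CTNNAL1 at -0.29, LAX1 at -0.27, HDDC3 at -0.26 and GSTM2 at -0.26 each lost theirs in 8 or more of 12 fits without 1 array, LAX1 in all 12 (up to 0.165). GSTM2 has close paralogs whose transcripts its probes could share. For CYP27B1, RXRA, ESR1 and ESR2 the changes were -0.07, -0.09, -0.04 and 0.04 (adjusted p = 0.914, 0.831, 0.954 and 0.945). In all, limma called 160 probe sets, 144 higher and 16 lower, and 23 of the 24 named rises were seen in 6 of 6 arrays. That count fell to 99 without array 1 of GM10855 with both agents, to 102 without array 1 of GM10861 with estrogen and to 103 without array 1 of GM10861 with both agents. Several of the falls named here were not seen in calcitriol against untreated, where HAPLN3 gave 0.015, HDDC3 0.038, CDC25C -0.0081 and GSTM2 -0.014. CTNNAL1 gave -0.24, LAX1 -0.20 and CD109 -0.19 there, also without being called.

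Gene lists in calcitriol added to estrogen gave 10 past camera, 7 higher and 3 lower, and 0 with an estimated correlation in limma. Of the 7 higher lists 2 lost their call without at least 1 array, as did 2 of the 3 lower ones. Of 36 VDR targets 4 rose (6 adjusted over the list alone), CAMP, CYP24A1, G0S2 (0.45, adjusted p = 6.31e-04) and VDR, with a list adjusted p = 8.32e-05 (adjusted p = 0.0821 with an estimated correlation). Plasma cell markers CD38 and TNFRSF17 (0.68, adjusted p = 9.06e-09) were 2 of 15 that rose (4 adjusted over the list alone; adjusted p = 0.0821 with an estimated correlation). B cell markers CD79A, CR2 (0.43, adjusted p = 2.7e-04) and PAX5 (0.32, adjusted p = 0.00239) were 3 of 18 (4 adjusted over the list alone; adjusted p = 0.199 with an estimated correlation). LGMN rose among MHC class II genes (0.66, adjusted p = 1.84e-07; list adjusted p = 0.228 with an estimated correlation), CCL22 among NF-kB targets (0.49, adjusted p = 0.00896; list adjusted p = 0.638 with an estimated correlation), and IL2RA (0.29, adjusted p = 0.0177) with IRF8 (0.26, adjusted p = 0.0343) among the autoimmune genes (list adjusted p = 0.352 with an estimated correlation). IL2RA lost its call in 3 of 12 fits without 1 array (up to 0.0682) and IRF8 in 8 (up to 0.145). CYP19A1 rose by 0.41 (adjusted p = 0.0137), lost in 3 of 12 such fits (up to 0.0569). DDIT4 (0.37), PHGDH (0.27), the chaperone-binding gene CHORDC1 (0.29) and GCLC, the first enzyme of glutathione synthesis (0.35), rose in lists that did not pass, and lost their calls in 5, 4, 11 and 9 of 12 fits without 1 array (up to 0.0607, 0.0574, 0.167 and 0.167). The vitamin D metabolism list, with CYP24A1 and VDR as its 2 rises (2 adjusted over the list alone), had an adjusted p = 0.0228 (adjusted p = 0.199 with an estimated correlation). Leaning lower were 33 oxidative phosphorylation genes (mean -0.0664), 32 cytosolic ribosomal proteins (mean -0.0519) and 30 G1/S and DNA replication genes (mean -0.0480), each with 0 called members in limma and 0 adjusted over the list alone (adjusted p = 0.638, 0.730 and 0.638 with an estimated correlation).

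Calcitriol against untreated and calcitriol added to estrogen share no array. Of their 144 and 160 called probe sets, 98 were called in both, 95 higher and 3 lower, where independent lists would share 0.889 and 0.0098; 0 were called in opposite directions. The change had the same sign in both comparisons for 143 of the 144 (99.3%), with a correlation of 0.961 across those probe sets and a slope of 0.902. The correlation and the slope lean most on the largest changes, such as those of CAMP, CYP24A1 and STS. Across all 21214 probe sets, which are not independent replicates, the correlation was 0.284. Because a single spread estimate served both contrasts, the fits were repeated on 12 arrays each, which called 101 and 99 and shared 64.

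**Figure D2:**
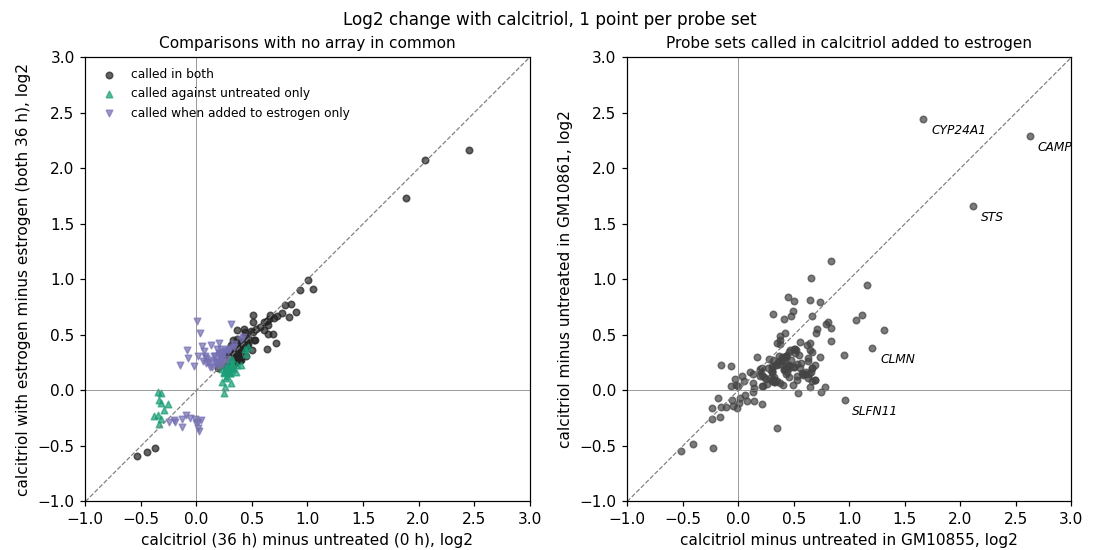
Left, log2 change in calcitriol against untreated (horizontal) and in calcitriol added to estrogen (vertical) for the 206 probe sets called in either, of which 98 were called in both, 46 against untreated alone and 62 with estrogen alone; dashed lines mark equal change. Right, change against untreated in GM10855 (horizontal) and GM10861 (vertical) for the 160 probe sets called in calcitriol added to estrogen, with CLMN (1.21 and 0.38) and SLFN11 (0.96 and -0.08) below the dashed line.

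Cells given both agents were also compared with untreated cells. CAMP rose 4.89-fold in calcitriol and estrogen against untreated (2.29 ± 0.102, adjusted p = 5.74e-13), CYP24A1 by 2.10, STS by 1.92, CD38 by 1.01 and VDR by 0.37 (adjusted p = 0.00156). ZNF589 (0.98), DENND6B (0.94), LGMN (0.85), CLMN (0.82), CD79A (0.81) and SULF2 (0.74) followed, and all 11 of these rises kept their calls in every setting that tested them, the minimum change of 0.5 aside; the filter on dim probe sets left out CYP24A1. HGF fell by 0.67 on the log2 scale (adjusted p = 3.01e-04), ANXA1 by 0.57 (adjusted p = 1.31e-04) and FRMD6 by 0.36, which kept their calls on the same terms, HGF without a test under the dim filter. CCR2 at -0.43, the chemokine gene CCL25 at -0.42, the histone gene H2AC12 at -0.40, the interferon-induced IFIT1 at -0.35, CTNNAL1 at -0.33, TOX at -0.32 and the calpain gene CAPN2 at -0.32 were lower too, and each lost its call in at least 1 alternative (adjusted p up to 0.0578, 0.486, 0.149, 0.342, 0.0569, 0.440 and 0.214). In all, limma called 243 probe sets, 211 higher and 32 lower, of which 8 were small RNAs; the count was 134 without the 3 arrays farthest from their group means. Of 31 lists 14 passed, 9 higher and 5 lower, and 0 with an estimated correlation in limma (smallest adjusted p = 0.187 with an estimated correlation). The 6 VDR targets that rose (7 adjusted over the list alone) and the 3 B cell markers (4 adjusted over the list alone) stood beside 32 ribosomal proteins with a mean of -0.0897 and 33 oxidative phosphorylation genes with a mean of -0.0817, of which 0 were called or passed adjusted over the list alone (adjusted p = 0.348 and 0.348 with an estimated correlation).

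Estrogen alone changed no gene past the threshold. The smallest p values in estrogen against untreated belonged to the potassium channel gene KCNQ5 (0.24, adjusted p = 0.573), the T cell receptor zeta chain gene CD247 (0.28, adjusted p = 0.573) and the hydrolase gene FHIT (0.33, adjusted p = 0.573) on the higher side. On the lower side were the transporter gene SLC10A5 (-0.36, adjusted p = 0.266), MPLKIP (-0.26, adjusted p = 0.573) and the ribosome assembly factor BRIX1 (-0.29, adjusted p = 0.580). ESR1 gave -0.02 and ESR2 -0.06 (adjusted p = 0.997 and 0.983). In limma 0 probe sets passed (smallest adjusted p = 0.0717, for a probe set outside the naming rule), while 1097 had an unadjusted p under 0.05. Of 27 estrogen response genes 0 passed, also adjusted over the list alone (mean 0.0186, list adjusted p = 0.889). The 33 hypoxia and glycolysis genes leaned higher (mean 0.0578, adjusted p = 0.0226) and the 32 cytosolic ribosomal proteins lower (mean -0.0378, adjusted p = 0.0101), with 0 called members each, 0 adjusted over the list alone, and an adjusted p = 0.957 with an estimated correlation for both. Their calls were lost in 5 and 3 of 12 fits without 1 array, and the count of 0 probe sets became 3 with a filter on dim probe sets, 6 with eBayes trend and robust estimation, 3 without untreated array 3 of GM10855 and 3 without estrogen array 2 of GM10855.

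Estrogen added to calcitriol, with both groups at 36 h, likewise gave 0 calls in limma (smallest adjusted p = 0.115; 1772 probe sets at an unadjusted p under 0.05). TAF1L (0.29, adjusted p = 0.115), NF1, a regulator of RAS (0.32, adjusted p = 0.115), and the taste receptor gene TAS2R14 (0.48, adjusted p = 0.408) had the smallest p values upward, and MRM3 (-0.25), HAPLN3 (-0.29) and URM1 (-0.19) downward (adjusted p = 0.408, 0.408 and 0.409). The 32 ribosomal proteins (mean -0.0830) and 33 oxidative phosphorylation genes (mean -0.0850) passed camera toward lower expression, each with an adjusted p = 3.91e-06 and an adjusted p = 0.767 with an estimated correlation. In neither list was a member called over all probe sets (0 each), and adjusted over the list alone 0 ribosomal proteins and 1 oxidative phosphorylation gene were lower. The count of 0 became 1 without array 2 of GM10855 with both agents, 2 with a filter on dim probe sets, 1 with array weights and 3 without the 3 arrays farthest from their group means. Whether both agents together differed from the sum of their single effects was tested as the interaction of calcitriol and estrogen, which gave 0 calls in limma (smallest adjusted p = 0.671, 935 at an unadjusted p under 0.05). CAMP had an interaction of -0.30 ± 0.145 (adjusted p = 0.992) and CYP24A1 of 0.02 (adjusted p = 0.995). The smallest p values belonged to ZNF26 (0.38), TAF1L (0.33), RIN2 (0.38), MRM3 (-0.30), PLCD4 (-0.32) and URB1-AS1 (-0.32), with an adjusted p = 0.671 for ZNF26 and 0.992 for the others. Hypoxia genes (mean -0.0909, adjusted p = 0.00133) and oxidative phosphorylation genes (mean -0.0697, adjusted p = 0.0139) passed camera, with 0 members called or passing adjusted over the list alone and an adjusted p = 0.994 with an estimated correlation for both. The first call was lost without array 3 of GM10861 with estrogen (adjusted p = 0.0664) and the second in 9 of 24 fits without 1 array (up to 0.287). The interaction has a median standard error of 0.105 and holds the effect of time in culture, which does not cancel in it.

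The response to calcitriol was next compared between the lines. SLFN11, a DNA damage response gene, rose in GM10855 by 0.96 and gave -0.08 in GM10861 in calcitriol against untreated, a difference of -1.04 ± 0.130 (adjusted p = 0.00101). Its untreated level was 5.66 ± 0.182 in GM10855 and 7.41 ± 0.0730 in GM10861 (SD, n = 3). CLMN, which encodes calmin, rose by 1.21 in GM10855 and by 0.38 in GM10861, a difference of -0.83 ± 0.131 (adjusted p = 0.0223), and this call was lost in 8 of 12 fits without 1 array (up to 0.137). CYP24A1 had a larger change in GM10861 (2.44) than in GM10855 (1.67), but the difference of 0.78 ± 0.231 did not pass (adjusted p = 0.524), nor did that of CAMP at -0.33 (adjusted p = 0.796). SLFN11 and CLMN were the 2 probe sets called in limma for the line difference, with 1407 at an unadjusted p under 0.05, and the count was 1 in 8 of the 12 fits that left out 1 array, 10 with array weights, 7 with trend and robust estimation and 0 with only the arrays compared. Tested in each line by itself, calcitriol against untreated called 108 probe sets in GM10855, 103 higher and 5 lower, and 22 in GM10861, 21 higher and 1 lower. The count for GM10855 was 70 without untreated array 2 of that line and 53 without the 3 arrays farthest from their group means, which leaves 1 untreated array of that line, assumed to vary like the other groups. The counts of 108 and 22 rest on a spread pooled over the lines, although the median replicate SD was 0.137 in GM10855 and 0.115 in GM10861. Pooling favours calls in the line with the larger spread, so these counts are not on equal terms. Fits of only the arrays compared, with each line's own spread, gave 39 calls in GM10855 and 16 in GM10861. For estrogen against untreated the line difference gave 0 calls in limma (smallest adjusted p = 0.654, 1257 at an unadjusted p under 0.05).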

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

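The counts over other splits of the arrays were planned, whereas the splits with other responses taken off, the line differences with both agents against untreated and in calcitriol added to estrogen, and the tests of time in culture, of the response to calcitriol and of the larger response in GM10855 were chosen after the results were seen.

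SLFN11 differed between the lines, with responses to calcitriol against untreated of 0.96 in GM10855 and -0.08 in GM10861 (difference -1.04, adjusted p = 0.00101) and, with both agents against untreated, a difference of -0.90 (adjusted p = 0.00573). In calcitriol added to estrogen, at matched times, its difference of -0.65 did not pass (adjusted p = 0.140, from 0.85 in GM10855 to 0.20 in GM10861). CLMN differed by -0.83 in calcitriol against untreated (adjusted p = 0.0223), by -0.91 with both agents against untreated (adjusted p = 0.00573) and by -0.998 in calcitriol added to estrogen (adjusted p = 0.00239, from 1.27 in GM10855 to 0.27 in GM10861). ENTPD7 differed by -0.72 with both agents against untreated (adjusted p = 0.0294), from 0.81 to 0.09. Single arrays were compared by their residuals over all groups (root mean square 0.101 to 0.145), not tested within a group of 3.

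In the line difference in calcitriol against untreated, 10 gene lists passed camera. GM10861 had the lower mean response for G1/S genes (-0.117), G2/M genes (-0.150), the unfolded protein response (-0.168), ATF4 targets (-0.103), fatty acid synthesis (-0.159), ribosome biogenesis and MYC targets (-0.141), heat shock genes (-0.173), NRF2 targets (-0.135) and TFEB targets (-0.125), and the higher one for monocyte markers (0.0830). In the line difference in estrogen against untreated, ribosome biogenesis and MYC targets passed (-0.0877). With an estimated correlation 0 of these 11 lists passed in limma, the smallest adjusted p being 0.265 for calcitriol and 0.75 for estrogen. The line difference put 1 list past camera in calcitriol added to estrogen, at matched times, and 2 with both agents against untreated. Most of the 10 lists therefore did not pass in either.

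Among the 12083 probe sets unnamed here, which none of the comparisons above used, 10 were called in calcitriol against untreated (9 higher, up to 1.13), 42 with both agents against untreated (30 higher, 12 lower) and 12 in calcitriol added to estrogen (all higher, up to 1.66); 5 were called in both calcitriol comparisons.

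For calcitriol against untreated, 1 of 100 splits of the arrays, the real one, reached its 144 calls (highest other 40), and 3 of 100 reached its 15 gene lists, although another split gave 21. With both agents against untreated, 1 of 100 splits reached the 243 calls (highest other 128) and 1 of 100 the 14 lists (highest other 10), and in calcitriol added to estrogen 1 of 100 reached the 160 calls (highest other 35) and 1 of 100 the 10 lists (highest other 8). By the share of splits, chance can be excluded for the counts of calls, which without 1 array stayed above every other split (lowest 96, 165 and 99). For the lists chance is left open. Without 1 array the lists numbered 10 to 16 in calcitriol against untreated (highest other 21). In calcitriol added to estrogen they numbered 7 to 12 (highest other 8). With both agents against untreated they numbered 11 to 14, but with an estimated correlation 0 of the 14 passed, 0 of the 10 and 3 of the 15. Splits of arrays that may be technical replicates cannot exclude chance between cultures. Chance also cannot be excluded for the 2 lists of estrogen against untreated (46 of 100 splits, highest other 16), of estrogen added to calcitriol (53 of 100, highest other 9) and of the interaction (56 of 100, highest other 15, and 46 of 100, highest other 14, with the single responses to calcitriol and estrogen taken off). Splits with several times the real number of lists point to a structure of the arrays or to a correlation within lists above the preset one, and neither was tested over the splits. For the 0 calls of estrogen against untreated, estrogen added to calcitriol, the interaction and the line difference in the estrogen response, 100 of 100 splits must reach the count (highest other 2, 1, 3 and 2), so the splits say nothing there. For the line difference in calcitriol against untreated 17 of 100 splits reached the 2 calls (highest other 144, from a split that exchanges calcitriol and untreated arrays in 1 line and so counts the shared response). With the shared response taken off, 1 of 100 splits, the real one, reached 2 (highest other 1), but fits without 1 array gave 1 to 3 calls, so chance is left open for this count. Within GM10855 and within GM10861, 1 of 10 splits, the real one, reached the 108 and 22 calls (highest other 0 in each), and 10 splits are too few for a share under 0.05.

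Calls in calcitriol against untreated could come from 36 h in culture or from calcitriol. Time as the whole cause is argued against by calcitriol added to estrogen, where both groups were at 36 h: over the 144 called probe sets that change had a slope of 0.902 on the change against untreated (0.881 to 0.914 leaving out 1 array), where time alone would give a slope near 0. The same 144 probe sets, chosen with the untreated arrays, were then followed with no untreated array in either change. The estrogen arrays were parted so that the changes shared no array. The median slope over 9 partings was 0.956 (0.913 to 1.02), as a response to calcitriol would give. Probe sets changed by time alone would add little to either change, so this slope cannot tell what share of the 144 responded to calcitriol. Both slopes weight a probe set by its squared change, so the largest changes count most. At matched times 98 of the 144 were called and 46 were not. A calcitriol response may therefore account for most of the larger changes, while the share among the smaller ones is not settled. A part due to time, for single genes or in the comparisons of estrogen with untreated cells, stays open.

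The 160 probe sets called in calcitriol added to estrogen had a larger mean change against untreated in GM10855 (0.458, signed by direction) than in GM10861 (0.289), and 123 of them were larger in GM10855. The median replicate SD was higher in GM10855 (ratio 1.20, 1.15 to 1.24 leaving out 1 array), but noise bears on the number of calls and not on a mean change, so this ratio decides nothing here. The untreated arrays of GM10855, 2 of which lie far from their group mean, are argued against as the whole cause by a ratio between the lines with a median of 1.35 (1.26 to 1.48) over 9 fits without untreated arrays, where calcitriol was set against an estrogen array per line that had no part in choosing the probe sets, and by one of 1.40 (1.36 to 1.44) in calcitriol added to estrogen over the 144 probe sets called against untreated, a set chosen with them. A difference between the cell lines is a candidate explanation. The ratio of 1.59 (1.51 to 1.66) between the opening means of the 160 probe sets restates the pattern and is no separate support for it. With 2 lines, growth state or passage stays open beside genotype, and CYP24A1 had its larger change in GM10861 (difference 0.78, adjusted p = 0.524).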

How the results depend on the processing

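The fits without the 3 arrays farthest from their group means, and those with estrogen arrays as the reference, were tests chosen after seeing the data; the other settings given here were planned. Of 90 called results for named genes, 51 kept their call in every setting that tested them, 44 of 58 rises, 7 of 30 falls and 0 of 2 differences between the lines, and 0 reversed; the minimum change of 0.5 was not among these settings, and the filter on dim probe sets tested no gene below it. No paired analysis was possible because the labels carry no replicate numbers. Where a fit leaves 2 arrays in a group, their spread is taken as that of the other groups, and so is that of the lone untreated array of GM10855 left without the 3 arrays farthest from their group means. Signal over background limits the dim genes, VDR, CYP24A1, ESR1 and ESR2 among them, because no background level came with the values. The cause was not tested for any change below unless fewer arrays or fewer probe sets explain it.

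A minimum absolute log2 change of 0.5, stricter by construction, left 31 calls of 144 in calcitriol against untreated, 44 of 243 in calcitriol and estrogen against untreated, 36 of 160 in calcitriol added to estrogen and 65 of 108 in calcitriol against untreated in GM10855. Fitting only the arrays compared has fewer degrees of freedom and takes the spread from those arrays alone, and the part of each was not tested. It gave 138 calls in calcitriol and estrogen against untreated and 99 in calcitriol added to estrogen. Calcitriol against untreated then gave 39 calls in GM10855, 16 in GM10861 (22 in the main fit) and 0 in the line difference. With eBayes trend and robust estimation there were 6 in estrogen against untreated, 371 in calcitriol and estrogen against untreated, 7 in the line difference in calcitriol against untreated and 37 in calcitriol against untreated in GM10861. Array weights gave 1 in estrogen added to calcitriol, 10 in the line difference in calcitriol against untreated and 53 in calcitriol against untreated in GM10861. The filter on dim probe sets gave 3 in estrogen against untreated, 2 in estrogen added to calcitriol and 4 in the line difference in calcitriol against untreated, where all probe sets of the table gave 1. Cyclic loess gave 35 in calcitriol against untreated in GM10861. Without the 3 arrays farthest from their group means there were 134 in calcitriol and estrogen against untreated, 3 in estrogen added to calcitriol, 1 in the line difference in calcitriol against untreated and 53 in calcitriol against untreated in GM10855. With estrogen arrays at 36 h in place of the untreated arrays, calcitriol against untreated gave 121 calls, of which 95 were among the 144. An estimated correlation left 3 of 15 gene lists in calcitriol against untreated and 0 of 10 in calcitriol added to estrogen, while fry called 7, of which 6 were among the 15, and 5, all among the 10.

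Leaving out 1 array in turn gave 96 to 166 calls in calcitriol against untreated, 0 to 3 in estrogen against untreated, 165 to 314 in calcitriol and estrogen against untreated, 99 to 139 in calcitriol added to estrogen, 0 to 1 in estrogen added to calcitriol, 1 to 3 in the line difference in calcitriol against untreated, 70 to 151 in calcitriol against untreated in GM10855 and 18 to 21 in calcitriol against untreated in GM10861. The interaction and the line difference in estrogen against untreated stayed at 0 in limma throughout (0 to 0). Gene lists past the threshold numbered 10 to 16 in calcitriol against untreated and 7 to 12 in calcitriol added to estrogen.

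Sign changes were limited to values that passed no test. Leaving out 1 array, CYP27B1 ranged from -0.036 to 0.136 and ESR2 from -0.0077 to 0.0428 in calcitriol against untreated, ESR1 from -0.116 to 0.0277 in estrogen against untreated, ESR2 from -0.0131 to 0.0969 and ESR1 from -0.0941 to 0.0496 in calcitriol added to estrogen, and CYP24A1 from -0.0482 to 0.118 in the interaction of calcitriol and estrogen. ESR2, calcitriol against untreated, was -0.0194 with array weights and -0.0487 without the 3 arrays farthest from their group means, and ESR1, estrogen against untreated, 0.0188 without those arrays.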

Other observations

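The test of neighbouring genes, all fits of both agents against untreated in each line by itself, and the choice of the genes in the next paragraph, came after the results were seen.

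Among single genes that rose with calcitriol, STS and CYP19A1 act on other steroids. STS, which releases steroids from sulfate esters, rose from 5.03 ± 0.201 to 7.14 ± 0.0602 in GM10855 and from 5.87 ± 0.0365 to 7.54 ± 0.0185 in GM10861 (SD, n = 3), and CYP19A1, the aromatase, rose by 0.46 in calcitriol against untreated and 0.41 in calcitriol added to estrogen. The list that holds CYP19A1 did not pass in calcitriol against untreated (adjusted p = 0.531), and ESR1 and ESR2 did not pass in any comparison in which their values are given. With estrogen alone STS was 5.24 ± 0.115 in GM10855 and 6.04 ± 0.0282 in GM10861, 0.19 ± 0.0607 (SE) above untreated on average, which did not pass (adjusted p = 0.789).

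With both agents against untreated, GM10855 by itself gave 495 calls, 418 higher and 77 lower, and GM10861 gave 39, 36 higher and 3 lower. Both counts rest on the spread pooled over the lines, which favours calls in GM10855, the line with the larger replicate SD. In calcitriol and estrogen against untreated in GM10855 the count was 120 to 640 with 1 array left out, 66 without the 3 arrays farthest from their group means, all of which belong to that line (this leaves 2 arrays with both agents against 1 untreated array, assumed to vary like the other groups), 64 with only the arrays compared, 144 with a minimum change of 0.5, 194 with array weights and 770 with eBayes trend and robust estimation. In calcitriol and estrogen against untreated in GM10861 it was 20 to 24 with 1 array left out, more than 1.5 times below 39 in all 6 fits, 24 with only the arrays compared and 66 with array weights.

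Several genes that rose with calcitriol lie next to each other, and a hypothesis is that neighbours rise together. Among 120 genes that rose against untreated and stand in the order of 18365 genes, 4 pairs were adjacent, where 10000 random gene sets matched on mean signal held 0.866 pairs on average (permutation p = 0.0108, one-sided, adjusted 0.0167 over 2 tests). The pairs were CAMP with ZNF589, STS with PUDP, DENND6B with PLXNB2, and CD200 with BTLA. For calcitriol added to estrogen there were also 4 pairs (random mean 0.973, permutation p = 0.0167, one-sided): CAMP with ZNF589, CD200 with BTLA, G0S2 with LAMB3, and TXNDC11 with ZC3H7A. The hypothesis came from these same genes and 2 of the 4 pairs recur, so the p-values describe the gene sets, the second is no independent support, and the hypothesis stays open. Neighbours may share a regulatory element, although transcripts running on past a strong gene or probes that read both could give the same, and neither was tested.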
